A study of Homo sapiens with 7 samples.

How the data were processed

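Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in OCI-Ly7 cells, a human diffuse large B-cell lymphoma line, with antibodies against OCA-B, OCT2, OCT1, MED1, CREBBP and EP300, and an input library was sequenced beside them. Each factor had 1 library, so no value below has a replicate check. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, Bowtie2 2.3.2.2, SAMtools 1.3.1 and MACS2 2.1.1.20160309, and the genome build was hg38. Per the file headers, each ChIP file was called on its own against the same control file, in narrow mode, with an effective genome size of 2.7e+09, a q threshold of 0.05, a bandwidth of 300, a model fold range of 5 to 50 and 1 tag kept per position. Per the file headers, tags were 51 bp long and the control held 38884910 tags, of which 37517450 stayed after duplicates were removed. The ChIP libraries held 12357478 (CREBBP) to 34662045 (EP300) tags. The redundant rate was 0 for MED1 and CREBBP and 0.08 to 0.2 for the other factors. Whether duplicates had been removed from the MED1 and CREBBP files before peak calling was not tested, and no comparison of these lists with the others was adjusted for it.

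Each deposited list gives a peak's position, width and summit, the pileup signal at the summit, the −log10 p-value, the fold enrichment over the control and the −log10 q-value, all as the authors' peak caller wrote them. These values are the authors' and were used to describe, rank or filter peaks within a list. Some folds of several lists are printed side by side for 1 site or gene family. Depth, duplicate handling and antibody differ between the lists, so such folds do not rank the factors. Peaks of a list do not touch each other, and "region" below means 1 peak unless a merge is stated. Chromosomes 1 to 22 and X were used. Gene positions came from the RefSeq annotation of GRCh38.p14, which holds 19974 protein-coding and 18177 lncRNA genes on these chromosomes. The annotation used gives no strand and no exons. The design, fixed before the data were examined, spoke of transcription start sites, exons and introns. In their place a summit within 1 kb of either end of a protein-coding or lncRNA gene was called a gene boundary region, all other summits were called distal, and distal summits were split into those inside and those between genes. The planned comparison of DNA motifs under the summits was not run, since no genome sequence was used here.

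The share of list A overlapping list B by at least 1 bp was divided by its mean over 1000 random local shifts of list B (100 kb to 1 Mb either way, each chromosome moved as a block), with a one-sided permutation p and Benjamini-Hochberg adjustment over the 30 ordered pairs. Differences between shares carry 95% intervals from 10000 bootstrap draws of the 23 whole chromosomes. The intervals cover variation between chromosomes of these libraries only. OCT2 regions were split by overlap with OCA-B, and OCA-B regions without OCT2 formed the third class. Where one list was longer than the other it was also shortened to its strongest peaks by −log10 q. Distal MED1 regions were joined into clusters when within 10 kb, ranked by summed pileup, and the top 200 were compared with other clusters holding a similar number of MED1 regions (2000 bootstrap draws). The number was matched in bins of 1, 2, 3, 4, 5 to 6, 7 to 9 and 10 or more regions. For the gene lists, a distal region within 100 kb was given to the protein-coding gene with the nearest boundary. A gene was counted as having a region at its boundary where any part of a peak lay within 1 kb of either end. The summit was not used for this count, so a wide peak could count at a boundary and also as distal. The mean number per gene was placed among 10000 random lists of the same size matched on 10 bins of territory, which is the sequence nearer to that gene than to any other. These percentiles describe these libraries, since genes are not replicates. For BCL6, regions 50 to 350 kb upstream were counted and compared with the same window on both sides of every other protein-coding gene (39618 windows). The minus strand of BCL6 was taken from textbook knowledge.

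The gene lists, fixed before the data were examined, were germinal centre B cell, B cell identity, B cell receptor signalling, class II antigen presentation, plasma cell, CD40 and NF-kB response, cell cycle, ribosomal protein, replication-dependent H2B and other histone genes, small nuclear RNA genes, immunoglobulin V segments, and T cell, myeloid, erythroid, liver and neuron genes as lists of other cell types. The genes named were fixed by rule as well. List examples came from the first 4 members by number of distal OCT2 regions with OCA-B, or were members without any region. The other names were the nearest protein-coding genes of the 10 strongest peaks by fold in each list (−log10 q over 5), of the 10 regions in all 6 lists with the highest OCA-B fold, and of the first 15 MED1 clusters, the genes of the factors themselves with BCL6, and the 10 genes with the most distal OCT2 regions with OCA-B. Immunoglobulin genes and RNU2-1, given as neighbours of some of these regions, were chosen after the values were seen. Some genes that the rule selects are not reported here.

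Alternatives were the stronger 50% of each list, all lists shortened to the shortest, overlap of at least 50% of the shorter region, summits within 250 bp, other windows, joining and assignment distances, another ranking of clusters and other random backgrounds. Others were added after the data were seen and are named as such in the closing section. The code was tested on simulated data before use. Planted overlap of 29.9% between lists sized like OCA-B and OCT2 was recovered as 29.9%, 92 of 100 bootstrap intervals held a planted difference of 20 percentage points, and 6% of 200 random gene lists reached the 95th percentile. Lists made only of genes with large territories reached it too often with 10 bins, so 50 bins were added as an alternative. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.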

Results

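The genomic occupancy of OCA-B, OCT2, OCT1, MED1, CREBBP and EP300 was mapped by ChIP-seq in OCI-Ly7 cells, a line derived from diffuse large B-cell lymphoma. OCA-B, encoded by POU2AF1, is a lymphoid coactivator that is brought to octamer sites by the POU factors OCT2 (POU2F2) and OCT1 (POU2F1). MED1 is a subunit of Mediator, and CREBBP and EP300 are paralogous acetyltransferases. Each factor had 1 library, and all were called against a common input. The number of peaks on chromosomes 1 to 22 and X was 55361 for OCA-B, 73829 for OCT2, 23571 for OCT1, 43508 for MED1, 44585 for CREBBP and 82569 for EP300. After duplicate removal the libraries held 19965282 (OCA-B), 22142497 (OCT2), 22503613 (OCT1), 18459398 (MED1), 12357450 (CREBBP) and 27885791 (EP300) tags. The OCT1 list was thus the shortest although its library was deeper than all others except EP300. Median fold enrichment, as the authors' peak caller gave it, lay between 5.23 (MED1) and 6.602 (CREBBP), and median width between 287 bp (OCT2) and 349 bp (MED1).

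Many pairs of lists overlapped widely, although OCT1 lay at only 18.4% of EP300 and 21.4% of OCT2 regions. Of the OCA-B regions, 78.3% overlapped OCT2 (95% interval over chromosomes 75.6 to 80.4), 61.7% MED1 (59.6 to 63.5), 60.1% CREBBP (58.4 to 61.5), 81.7% EP300 (80.0 to 83.1) and 31.5% OCT1 (30.8 to 32.6). MED1 regions overlapped OCT2 in 80.1% and CREBBP in 70.4% of cases, and 92.1% of CREBBP regions overlapped EP300. When the lists were merged into 111561 regions, 52474 (47.0%) were in a single list and 10590 (9.49%) were in all 6. Among the regions in all 6 lists, the highest OCA-B folds were at LENG9 (89.8 for OCA-B, 57.4 for OCT2, 93.9 for OCT1 and 6.87 for MED1), HCN2 (75.4) and CD300LB (69.5). The gene boundary of PIM2, a survival kinase gene, had folds of 68.3 for OCA-B, 53.1 for OCT2 and 56.1 for OCT1.

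Each of the 30 ordered pairs of lists overlapped more than its locally shifted placements, at 15.3 times (EP300 with OCT1) to 29.4 times (CREBBP with MED1) the shifted share. The permutation p, adjusted over 30 pairs, was 0.001 for all, the smallest the 1000 shifts can give. The shifts test the placement of the lists and not replicate ChIP. Shifting by any distance along the chromosome moved 28 of the 30 ratios by over 1.5 times, to 23.6 to 50.3, summits within 250 bp moved 17 and lists shortened to the shortest moved 15, and all 30 stayed above the shifts.

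**Figure D1:**
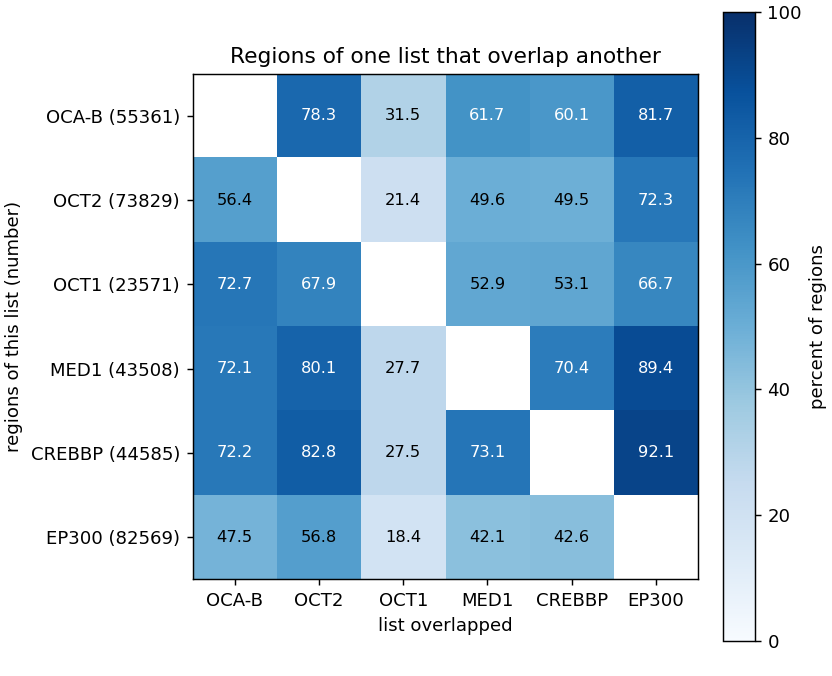
Percent of the regions of each list (rows, with the number of regions) that overlap by at least 1 bp each other list (columns), in OCI-Ly7 cells with 1 library per factor. OCT1 overlapped OCA-B in 72.7% and OCT2 in 67.9% of its regions, while 31.5% of OCA-B and 21.4% of OCT2 regions overlapped OCT1.

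OCA-B has no strong DNA contact of its own without a POU factor, and the next comparison asked which of these it accompanied. OCA-B regions overlapped OCT2 more often than OCT1, by 46.7 percentage points (43.1 to 49.4). Both were present at 15093 OCA-B regions (27.3%), OCT2 without OCT1 at 28227 (51.0%), OCT1 without OCT2 at 2367 (4.28%) and neither at 9674 (17.5%). The median OCA-B fold was 10.4 where both lay, 5.14 with OCT2 only, 5.95 with OCT1 only and 4.39 with neither. In the weakest decile of OCA-B regions by fold, 64.0% overlapped OCT2 and 5.54% OCT1, and in the strongest decile the shares were 96.9% and 91.5%.

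The OCT2 list was longer than the OCT1 list. With OCT2 shortened to the 23571 strongest peaks, the length of the OCT1 list, 43.5% of OCA-B regions overlapped OCT2 and the difference was 11.9 points (8.54 to 14.5). With both lists at the stronger 50% of the OCT1 length, an alternative chosen after the data were seen, it was 5.99 points (3.59 to 7.87). The result differed by place, a split chosen after the design was fixed. At the 40046 distal OCA-B regions OCT2 was ahead by 22.6 points (19.9 to 24.7), whereas at the 15315 gene boundary regions OCT1 was ahead, with 44.9% against 29.0%, and OCT2 minus OCT1 was −15.9 points (−19.2 to −13.2). With OCT2 in full, OCT2 was ahead in both places, by 55.7 points at distal and 23.2 points at gene boundary regions. OCT2 was shortened over all places together, so the lists were not of equal length within a place. Gene boundaries held 11.3% of shortened-list OCT2 peaks without OCT1 and 24.4% of OCT1 peaks with OCT2, against 40.0% of all OCT1 peaks. The lead of either factor in a place therefore cannot be told apart from its number of peaks there.

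**Figure D2:**
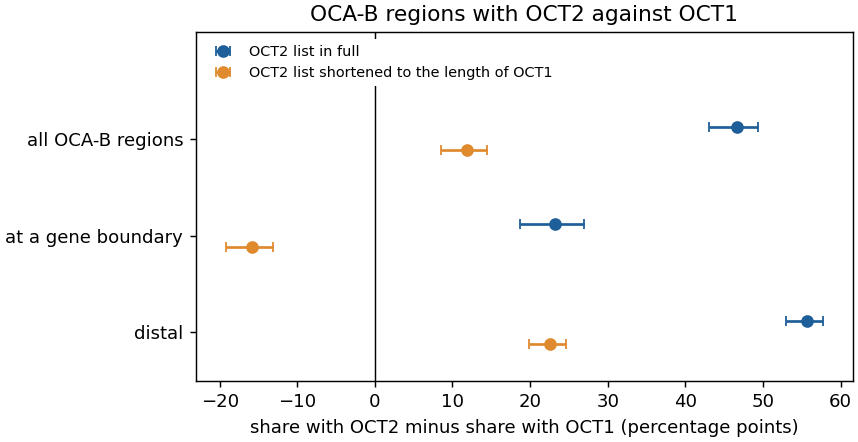
Share of OCA-B regions overlapping OCT2 minus the share overlapping OCT1, in percentage points, for all, gene boundary and distal OCA-B regions. Points are the differences and bars the 95% chromosome-bootstrap intervals, with the OCT2 list in full (blue) and shortened to the length of OCT1 (orange). At gene boundaries the sign depended on the length of the OCT2 list (23.2 and −15.9 points).

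Coactivators lay far more often at OCT2 regions that also held OCA-B. MED1 was found at 72.4% of the 41676 OCT2 regions with OCA-B, at 20.2% of the 32153 OCT2 regions without OCA-B and at 19.8% of the 12041 OCA-B regions without OCT2. For CREBBP the shares were 71.9%, 20.5% and 15.7%, and for EP300 they were 89.9%, 49.5% and 51.8%. All 3 coactivators were present at 62.7% of OCT2 regions with OCA-B, against 10.2% of those without and 7.24% of OCA-B regions without OCT2. The difference between OCT2 regions with and without OCA-B was 52.2 points for MED1 (51.3 to 53.0), 51.4 for CREBBP (50.4 to 52.3) and 40.4 for EP300 (39.8 to 41.0). Against OCA-B regions without OCT2 it was 52.5, 56.2 and 38.0 points. At distal regions the MED1 difference between OCT2 with and without OCA-B was 52.8 points, and at gene boundaries it was 45.5 points. The classes were made by splitting on lists that the coactivators overlap widely. OCA-B lay at 72.1% of MED1, 72.2% of CREBBP and 47.5% of EP300 regions, and OCT2 at 80.1%, 82.8% and 56.8%. Wide differences between the classes therefore followed in part from the split.

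OCT2 regions with OCA-B were stronger (median OCT2 fold 7.88 against 4.73) and wider (median 402 against 212 bp). Within quintiles of OCT2 fold the MED1 difference averaged 49.2 points (48.21 to 50.03). From the weakest to the strongest quintile, the MED1 share rose from 59.0% to 84.5% with OCA-B and was 26.3% and 19.4% without it. Within quintiles of OCT2 width, an alternative chosen after the data were seen, it averaged 35.4 points.

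**Figure D3:**
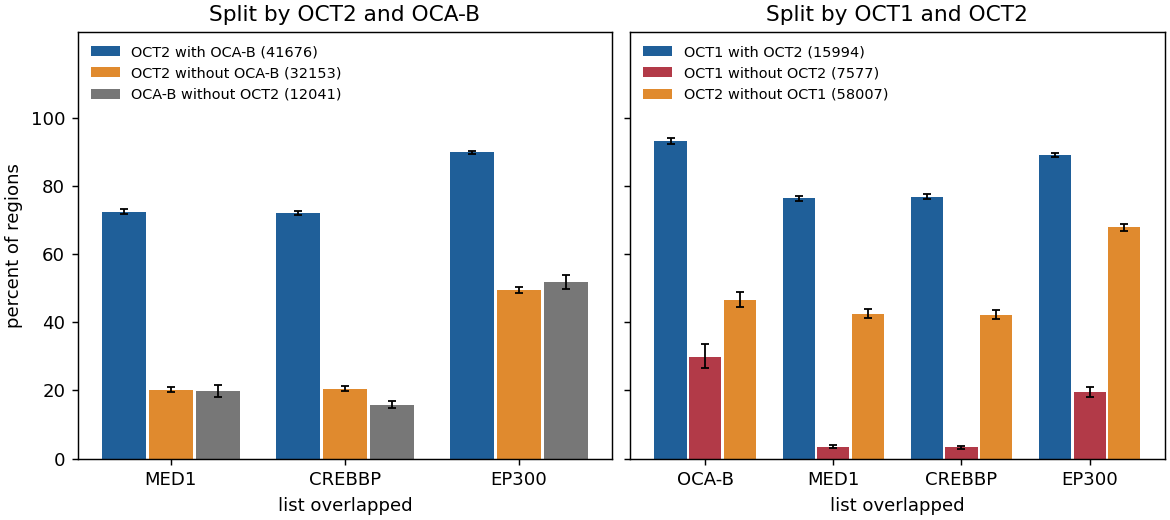
Percent of regions in each class (number of regions in brackets) that overlap each list, with 95% chromosome-bootstrap intervals as error bars. Left, OCT2 and OCA-B regions, where MED1 lay at 72.4%, 20.2% and 19.8% of the classes. Right, OCT1 and OCT2 regions, where MED1 lay at 76.3%, 3.58% and 42.5%.

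OCT1 and OCT2 read the same octamer sequence. OCT1 regions with OCT2 (15994) held OCA-B in 93.0%, MED1 in 76.3%, CREBBP in 76.7% and EP300 in 89.0% of cases. The 7577 OCT1 regions without OCT2 held OCA-B in 29.8%, MED1 in 3.58%, CREBBP in 3.37% and EP300 in 19.6%, and 59.2% of them lay at gene boundaries. OCT2 regions without OCT1 (58007) held OCA-B in 46.5%, MED1 in 42.5%, CREBBP in 42.2% and EP300 in 67.9%, and 14.5% lay at gene boundaries. OCT1 regions without OCT2 were above OCT2 regions without OCT1 by 44.8 points in gene boundary share (42.8 to 46.6) and below them in MED1 share, with a difference of −38.9 points (−40.3 to −37.6). OCT2 lay at 80.1% of MED1 regions and OCT1 at 27.7%. Leaving out OCT2 thus took away more MED1 than leaving out OCT1, and the MED1 difference was set in part by the split. With OCT2 shortened to the length of OCT1, OCT1 regions without OCT2 held MED1 in 16.9% and OCA-B in 45.9% of cases, OCT2 regions without OCT1 in 70.1% and 84.5%, and the OCA-B difference grew from −16.7 to −38.6 points. Shortening kept the strongest OCT2 peaks, and the median fold of OCT2 regions without OCT1 rose from 5.30 to 10.9. The OCA-B share of OCT2 peaks rose from 32.7% in the weakest to 98.0% in the strongest decile by fold. The growth therefore does not strengthen the contrast.

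Most CREBBP regions overlapped the longer EP300 list. EP300 lay at 92.1% of CREBBP regions and CREBBP at 42.6% of EP300 regions, and with EP300 shortened to the length of CREBBP the shares were 82.6% and 68.4%. Regions with both (41070) overlapped OCT2 in 87.3%, OCA-B in 76.3% and MED1 in 77.4% of cases. The 3515 CREBBP regions without EP300 overlapped OCT2 in 30.3%, OCA-B in 24.6% and MED1 in 23.7%, and the 47374 EP300 regions without CREBBP in 33.1%, 24.2% and 16.1%. CREBBP regions without EP300 were above EP300 regions without CREBBP by 7.56 points for MED1 (5.43 to 9.75) and by 8.85 points for gene boundaries (7.36 to 10.3). For OCA-B the interval of the difference included 0 (0.472 points, −2.20 to 2.76), and for OCT1 the difference was −3.00 points (−4.08 to −1.81). With EP300 shortened to the length of CREBBP, an alternative chosen after the data were seen, the MED1 difference was 20.8 points (18.7 to 22.9) and the OCT1 difference −6.07 points (−7.31 to −4.97). With all lists shortened to the shortest, the MED1 difference was 37.1 and that for gene boundaries 24.0 points, the OCA-B difference was 21.5 points with an interval above 0, and the OCT1 difference turned to 13.7 points. With summits within 250 bp the gene boundary difference was 1.63 points.

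OCT1 had the highest share of gene boundary regions, 40.0% (37.6 to 42.5), followed by OCA-B with 27.7%, MED1 with 22.9%, CREBBP with 20.4%, EP300 with 18.7% and OCT2 with 18.3%. Shifted regions gave 6.18% to 6.98%. The share of OCT1 was above that of OCT2 by 21.7 points (20.5 to 22.7) and that of OCA-B was above OCT2 by 9.35 points (8.81 to 9.84). Distal summits lay inside a gene in 38.3% (OCT1) to 55.8% (EP300) of all peaks. The difference of 0.338 points between EP300 and OCT2 turned to −2.07 points with all lists shortened to the shortest, and that of 2.11 points between CREBBP and OCT2 fell to 0.193 points in the stronger 50% of each list, with an interval that included 0.

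Small nuclear RNA and replication-dependent histone genes were mostly occupied at their boundaries, and immunoglobulin V segments in part. All 20 small nuclear RNA and related genes had a region within 1 kb in each of the 6 lists, with median highest folds of 34.8 for OCT2, 15.5 for OCA-B and 14.8 for OCT1. Counted for each factor on its own, so not always over the same genes, 16 of the 18 replication-dependent H2B genes had OCA-B, 16 OCT2, 16 MED1, 15 OCT1, 15 CREBBP and 15 EP300. Of the 51 other replication-dependent histone genes, counted in the same way, 46 had OCT2, 46 MED1, 45 OCA-B, 45 EP300, 44 OCT1 and 44 CREBBP. The median highest MED1 fold was 48.2 at H2B and 43.3 at other histone genes. H2BC21 (70.5), H3C3 (69.5), H2AC6 (67.3) and H3C15 (65.6) were nearest to 4 of the 10 strongest MED1 peaks. Of the 133 immunoglobulin V segments, 86 (64.7%) had OCT2, 86 EP300, 77 (57.9%) OCA-B, 66 CREBBP, 62 MED1 and 47 (35.3%) OCT1. Near-identical copies in these families share reads, so the count per copy is uncertain.

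Some of the 10 strongest peaks by fold lay at or near immunoglobulin genes in every list except OCT1. A peak 10.4 kb from the constant segment IGHA1, at chromosome 14 from 105696200 to 105696734 (nearest protein-coding gene TMEM121), was the strongest EP300 peak with a fold of 91.1. The same site had folds of 84.8 for OCT2, 66.5 for OCA-B, 100.3 for CREBBP, 87.3 for MED1 and 21.3 for OCT1. The strongest MED1 peak (fold 108.5) lay over the V segment IGKV4-1 at chromosome 2 from 88879749 to 88886575 (nearest protein-coding gene RPIA). OCT2 was strongest at FAIM (89.2), CREBBP at a region nearest to CRLF2 (132.3) and OCA-B at LENG9. OCT1 was strongest at a region nearest to PPP4R3C (127.0), then inside UBE3A (125.8) and inside KAZN (117.5).

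The 33545 distal MED1 regions formed 13842 clusters, of which 7755 held 1 region. The top 200 by summed pileup held 3707 regions (11.1%) and 16.3% of the pileup, with a median length of 34.9 kb and a median of 17 MED1 regions, and 199 of them contained all of the other 5 factors. The second covered 78.1 kb at FAM167A (47 MED1 regions), the third overlapped RPIA and IGKC (60 regions), the fourth was nearest to ID3 (40), an inhibitor of E proteins, and the fifth lay at ST6GAL1 (36), a sialyltransferase gene of B cells. The seventh lay from 187898698 to 188002506 on chromosome 3 (33 regions), between BCL6 and LPP. Others of the first 15 were nearest to TMEM121, GAB1, IGLL5, DTX1, CFAP251, DUSP22 and DEPTOR. The first cluster, nearest to CCDC200 (chromosome 17 from 43232428 to 43339251, 39 regions), covered RNU2-1 and 12 further small nuclear RNA genes, a tandem array of near-identical copies.

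Top clusters contained OCT1 more often than other clusters in the same bins of MED1 region number (99.5% against 94.2%, 5.29 points, 3.08 to 7.85). The last bin held all 457 clusters of 10 to 60 regions. The OCT1 share rose from 24.6% of clusters with 1 region to 96.9% in that bin, so the difference was not freed from size. For the other factors both shares lay between 98.97% and 100%, which left little room for a difference. Single MED1 regions overlapped OCA-B less often inside the top clusters (56.5%) than in other clusters (70.5%), a difference of −14.0 points (−17.1 to −10.5). The difference was −14.5 points for OCT2, −11.5 for CREBBP and −4.65 for EP300, and for OCT1 its interval included 0 (−0.783, −2.38 to 1.07). For OCT1 the cluster difference was 1.62 points with gene boundary regions kept and 16.3 points in the stronger 50% of each list.

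Genes of germinal centre B cells and of B cell receptor signalling had the most distal OCT2 regions with OCA-B. All 24 germinal centre genes had an OCT2 region with OCA-B at a boundary or distal, the count of genes given for each list below, with a mean of 11.96 distal regions per gene against 1.70 in matched random lists. Their first members were P2RY8 (32), KLHL6 (30), the transcription factor FOXO1 (28) and BACH2 (25). B cell receptor signalling genes had a mean of 9.70 against 1.82 (20 of 20 genes), led by PLCG2 (35), SYK (26), LYN (21) and PIK3AP1 (21). B cell identity genes had 7.52 against 1.35 (25 of 25), led by IKZF1 (24), BLK (19) and PAX5 (19). Each of these lists stood at percentile 100 of the random lists. Plasma cell genes had 4.95 against 1.38 (17 of 20 genes, percentile 100), led by EDEM1 (15), CREB3L2 (11) and the J chain gene JCHAIN (9). CD40 and NF-kB response genes had 3.94 against 1.45 (14 of 18, percentile 99.8), led by TRAF1 (15), BIRC3 (9) and TNFAIP3 (9). By the share of genes with a region, the CD40 and NF-kB list (77.8% against 61.4% in random lists) was at percentile 92.5. The plasma cell list (85% against 59.1%) was at 99.3 and the other lists named so far at 100. The high counts were not particular to OCT2 with OCA-B. Germinal centre, B cell identity and B cell receptor signalling genes also stood at percentile 100 for distal regions of every factor taken alone. Germinal centre genes had a mean of 15.96 OCA-B and 21.8 OCT2 regions against 2.17 and 3.28. They had 14.5 MED1 and 14.8 CREBBP regions against 1.84 and 1.92, and 4.92 OCT1 and 21.8 EP300 regions against 0.731 and 3.65.

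Class II antigen presentation genes did not stand apart in distal OCT2 regions with OCA-B, with a mean of 1.08 against 0.946 (8 of 13 genes, percentile 66.5). Their regulator CIITA had 7 regions, and HLA-DRB1 had none in any list. Reads of the HLA genes can also align to alternate contigs of chromosome 6, which held 104 (OCT1) to 733 (EP300) peaks and were not used. Cell cycle genes had 1.40 against 0.848 (percentile 90.3), and all 20 of them had OCT1 and OCA-B at a gene boundary, against 41.9% and 46.2% of all protein-coding genes. Ribosomal protein genes had 1.40 against 0.580 (percentile 98.1), led by RPL11 (8), and 19 of 20 had OCA-B at a boundary, where 46.2% of all protein-coding genes had it. H2B genes had 1.00 against 0.505 (percentile 93.3) and other histone genes 0.745 against 0.236 (percentile 99.98). Without matching on territory the percentiles of ribosomal protein and other histone genes were 59.0 and 3.92. By the share of genes with an OCT2 region with OCA-B, cell cycle genes (90% against 53.8% in matched random lists) were at percentile 99.96. H2B genes (83.3% against 47.4%) were at 99.93 and ribosomal protein genes (90% against 49.0%) at 99.985. Other histone genes (88.2% against 43.3%) were at 100 and class II genes (61.5% against 57.6%) at 60.8.

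Lists of other cell types were at or below their random lists. T cell genes had a mean of 1.10 against 1.45 (percentile 30.7), led by CD28 (9), myeloid genes 0.850 against 1.09 (percentile 36.2), erythroid genes 1.00 against 1.01 (percentile 56.0), liver genes 0.350 against 1.02 (percentile 2.58) and neuron genes 0.450 against 1.95 (percentile 0.315). Over all genes, ZCCHC7 (47), which neighbours PAX5, CUX1 (39), IGLL5 (39), FAM167A (38), RAPGEF1 (37) and PLCG2 (35) had the most distal OCT2 regions with OCA-B, followed by P2RY8 (32), RPIA (32), AKAP13 (31) and ARID5B (30). Of the factors' own genes, POU2F1 had 15, POU2AF1 10, POU2F2 10 and EP300 6, and MED1 and CREBBP had none.

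**Figure D4:**
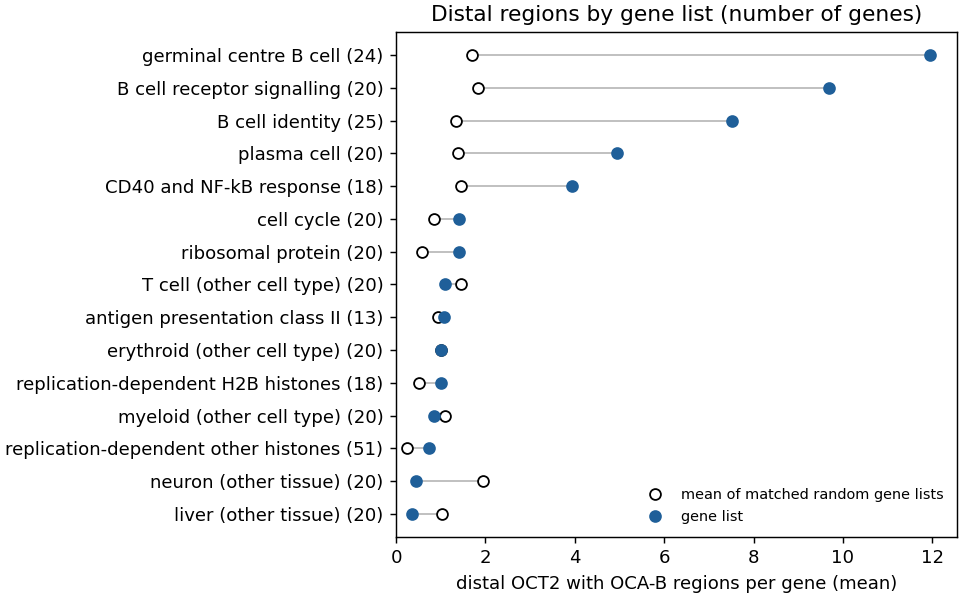
Mean number of distal OCT2 regions with OCA-B per gene for each gene list (filled points, number of genes in brackets) and the mean of 10000 random lists matched on territory (open points). Germinal centre genes had 11.96 against 1.70, neuron genes 0.450 against 1.95.

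BCL6, the transcriptional repressor that maintains germinal centre B cells, has a locus control region upstream, and the series title names such regions. The window 50 to 350 kb upstream of BCL6, from 187795468 to 188095468 on chromosome 3, overlaps no protein-coding gene and several lncRNA genes, among them LINC01991. It held 60 OCT2 regions (percentile 99.5 of 39618 windows beside other genes, whose median was 9), 46 OCA-B (98.3, median 7), 51 MED1 (99.4, median 4), 51 CREBBP (99.6, median 5), 67 EP300 (99.3, median 10) and 23 OCT1 regions (99.1, median 3). Merged over the lists these gave 67 regions, of which 18 held OCA-B, OCT2 and MED1 and 8 were in all 6 lists.

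The 8 regions in all 6 lists lay at 156, 173, 191, 202, 225, 255, 342 and 347 kb from BCL6. The longest ran from 187956507 to 187984021, with 15 OCA-B, 9 OCT2 and 12 OCT1 peaks and highest folds of 18.1 for OCA-B, 24.7 for OCT2, 27.7 for MED1 and 38.7 for CREBBP. The region from 187898664 to 187904580 had folds of 19.4 for OCA-B, 28.9 for OCT2 and 29.1 for OCT1. Close to BCL6 itself, all 6 factors had a region at a gene boundary. Neighbouring genes share windows, so the percentiles do not come from independent windows.

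**Figure D5:**
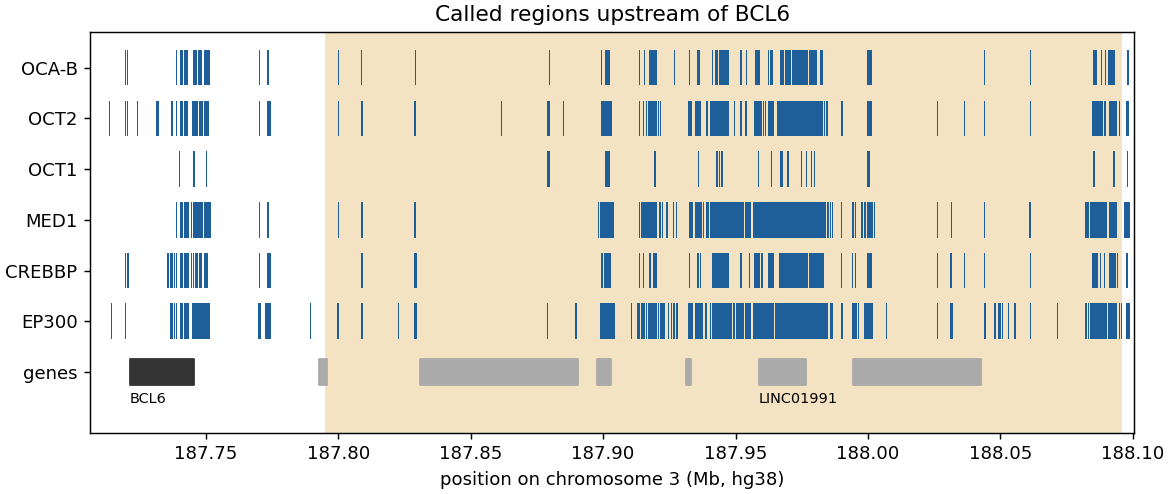
Peaks of each list (blue) along chromosome 3 (Mb, hg38) from BCL6 through the window 50 to 350 kb upstream (shaded). The bottom track shows BCL6 (dark) and lncRNA genes (grey). The window held 46 OCA-B, 60 OCT2, 23 OCT1, 51 MED1, 51 CREBBP and 67 EP300 regions.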

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

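The peaks counted in this part were tallied after the lists were examined. A signal appeared outside chromosomes 1 to 22 and X, in parts of the lists that the comparisons do not use. Peaks on alternate, unplaced or mitochondrial contigs numbered 1846 for OCA-B, 2174 for OCT2, 790 for OCT1, 1490 for MED1, 1534 for CREBBP and 2564 for EP300. Of these, 616 (OCA-B), 686 (OCT2), 104 (OCT1), 484 (MED1), 435 (CREBBP) and 733 (EP300) lay on alternate contigs of chromosome 6, and 131, 112, 60, 117, 111 and 141 on a single alternate contig of chromosome 14.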

How the results depend on the processing

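Alternatives chosen after the data were seen were the pairs shortened to their shorter list, the stronger 50% of the OCT1 length, EP300 shortened to CREBBP, OCT2 width quintiles, 50 territory bins and the clusters without the first. Over 89 results, 453 of 494 alternative values kept their direction and their side of the threshold, among them all coactivator differences between OCT2 with and without OCA-B and all BCL6 percentiles. The ratios of single pairs, all far above 1, had little room to change and raise this count. Without these ratios, the differences at single MED1 regions and the percentiles of single gene lists, 157 of 184 values did so and 18 changed direction. All 30 pairs of lists stayed above the shifts (200 per alternative), and 7 gene lists reached percentile 95 (5 to 8 under alternatives). The motif alternatives were not run. With 1 library per factor, depth and antibody cannot be separated from the factor. Where no construction is named, the cause was not tested.

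OCT2 minus OCT1 at gene boundary OCA-B regions (23.2 points) became −15.9 with OCT2 shortened to OCT1, by construction from a shorter OCT2 list. It was −21.1 with all lists shortened, which shortens OCA-B too, and −14.7 with OCT2 and OCT1 both at the stronger 50% of the OCT1 length. OCT1 with OCT2 minus the converse (46.4) was 3.17 with OCT2 shortened to OCT1 and 3.17 with all lists shortened. For CREBBP without EP300 minus EP300 without CREBBP, OCA-B (0.472) was 12.3 in the stronger 50%, 21.5 with all lists shortened, −0.877 with 50% overlap and 15.0 by summits. OCT2 (−2.81) was 0.914 with EP300 shortened, 6.196, 12.6 and 14.7 in the stronger 50%, with all lists shortened and by summits, and OCT1 (−3.00) was 7.01, 13.7 and 3.30 in the same order, but −6.07 with EP300 shortened and −1.50 with 50% overlap. MED1 (7.56) kept its sign, from 9.98 with 50% overlap and 20.8 with EP300 shortened to 37.1 with all lists shortened.

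Gene boundary shares against OCT2 were 0.193 for CREBBP in the stronger 50% (2.11) and −2.07 for EP300 with all lists shortened (0.338). For top MED1 clusters, OCA-B (0.710) was −0.158 in the stronger 50% and 0.750 with 5 kb joining, OCT2 (−0.150) was 0.234 with 5 kb joining and 0.389 when ranked by number, CREBBP (0.706) was −0.155 in the stronger 50%, 0.778 when ranked by number and 0.0189 with boundary regions kept, and EP300 (0.531) was −0.177 and −0.280 in the stronger 50% and with boundary regions kept. OCT1 at single MED1 regions (−0.783) was 4.45 in the stronger 50% and 0.708 with 5 kb joining. Without matching on territory, percentiles were 42.8 for class II, 33.2 for H2B, 3.92 for other histone and 33.1 for erythroid genes, and erythroid genes were at 47.8 with 50 kb.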

Other observations

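The tests on OCT1 regions without OCT2, the tallies of the strongest peaks and the OCT2 width quintiles were chosen after the results were seen. Of the 50 strongest OCT1 peaks by fold, 94% overlapped OCT2 and 82% OCA-B, but 20% MED1, 16% CREBBP and 42% EP300. The 50 strongest OCT2 peaks overlapped MED1 in 92%, and the 50 strongest OCA-B peaks in 74%. Among the 10 strongest OCT1 peaks, those nearest to PPP4R3C, NFATC1, RYR1, KCNK1 and KIAA1217 had no MED1, CREBBP or EP300 peak. The low shares depended on the number of peaks taken. MED1 lay at 39% of the 200 strongest by fold, 53.4% of the strongest decile and 52.9% of all OCT1 regions. By decile of OCT1 fold the MED1 share was highest in the weakest (71.5%) and lowest in decile 6 (45.9%). For OCT2 peaks it was 38.1% in the weakest and 87.3% in the strongest decile. The ranking mattered too. By −log10 q and by pileup MED1 lay at 48% and 70% of the 50 strongest OCT1 peaks, where OCT2 peaks reached 100% in both.

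Gene boundaries of cell cycle genes held OCT1 without OCT2 in 10 of 20 genes and OCT1 with OCT2 in 12 of 20. For germinal centre genes the counts were 5 and 16 of 24, and for the other replication-dependent histone genes 0 and 44 of 51. Over all 19974 protein-coding genes the shares were 22.6% and 23.2%. These shares were not tested against each other.

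Strong OCT2 regions without OCA-B were few. In the strongest quintile of OCT2 regions by fold, 861 lacked OCA-B and 13904 had it. Those without OCA-B held MED1 in 19.4% and EP300 in 61.7%, against 84.5% and 95.2%. They were also weaker (median OCT2 fold 13.2 against 17.9), so the groups were not matched on strength. They were narrower (median 371 against 679 bp) and lay less often at gene boundaries (7.78% against 15.4%).

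OCA-B regions overlapped OCT2 more often than OCT1. The longer OCT2 list argues for part of the difference, and 11.9 points (8.54 to 14.5) stayed at equal length. Shortening kept the strongest OCT2 peaks but all OCT1 peaks. From the weakest to the strongest decile by fold, the OCA-B share went from 32.7% to 98.0% for OCT2 peaks and from 85.2% to 81.6% for OCT1 peaks. Shortening by strength therefore favoured OCT2, and the 11.9 points do not settle whether list length was the whole cause. The remainder was 5.99 points at the stronger 50% of the OCT1 length. It turned at gene boundaries, but OCT2 was shortened over all places together, so the split by place decides nothing. Antibody efficiency stays open, and no biological explanation was tested.

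MED1 lay more often at OCT2 regions that also held OCA-B. Within OCT2 fold quintiles the difference was 49.2 points, against 52.2 for all regions. From the weakest to the strongest quintile, the MED1 share went from 59.0% to 84.5% with OCA-B and from 26.3% to 19.4% without it. Quintiles did not match strength, since median OCT2 fold in the strongest was 17.9 with OCA-B and 13.2 without it. Whether stronger OCT2 peaks were the whole cause therefore stays open. Wider regions are unlikely as the whole cause, since summits within 250 bp left 47.4 points (46.4 to 48.2). Width quintiles lowered the difference to 35.4 points, so width may account for part. Open chromatin that raises all signals at once was not tested and stays open.

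OCT1 regions without OCT2 lay at gene boundaries in 59.2% of cases and held coactivators less often than OCT2 regions without OCT1, with MED1 at 3.58% and EP300 at 19.6%, or 16.9% and 37.0% with OCT2 shortened to the length of OCT1. They were weaker calls (median −log10 q 7.76 against 11.4 with OCT2). Within quintiles of −log10 q those without OCT2 stayed ahead in gene boundaries by 31.0 points (28.1 to 33.6). This counts against weak calls as the whole cause of the gene boundary share. Those with OCT2 stayed ahead in MED1 by 72.5 points (71.5 to 73.5), which decides nothing. The regions were split by the OCT2 list, which 80.1% of MED1 regions overlap, so a wide MED1 gap was set by the split. The MED1 gap to OCT2 regions without OCT1 was set in part as well, since only 27.7% of MED1 regions overlap OCT1. The ratio of median folds, without over with OCT2, was 1.02 and decides nothing, since peaks were called on q. Chromatin pulled down in any ChIP stays open, since the regions were selected for absence from the OCT2 list, which overlaps the other 4 lists widely, and the 35.1% found in any of these therefore decides nothing. A second target of the OCT1 antibody and OCT1 binding apart from OCA-B stay open too, and neither was tested.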
